A study of Mus musculus with 2 samples.

How the data were processed

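Total RNA from 2 biological replicates of mouse HSC was sequenced after depletion of ribosomal RNA, from 100 ng of RNA with the ScriptSeq kit, per the labels. The labels assign the replicates to separate biosamples and to the same strain entry. Whether they came from different animals is not given in the sources used here. For each library there was a gene table of 69691 features and a transcript table of 129984. Per the file headers, the deposited values are expected counts, which are estimated counts that need not be whole, TPM, FPKM, posterior mean versions of these, and interval bounds on the TPM scale, a score without a unit of its own. The transcript tables add the deposited isoform percent, the percent of a gene's TPM in a transcript. TPM was scaled by the authors to a constant sum over all features of a table. The tables were built on mm10 with GENCODE M4, per the sample text files, and the aligner and counter are not given in the sources used here. The width of the deposited bounds implied a level of about 95% (95.0 in each library).

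Gene names, classes and positions came from GENCODE M21, matched by identifier without version for 42462 of 43346 genes. The 884 genes without a match held 0.253% of counts in replicate 1 and 0.231% in replicate 2. Another 26248 features with numeric identifiers and 97 spike-in sequences were left out of gene lists, and the spike-in sequences had 0 counts. The mean fragment length implied by the effective lengths was 193 nucleotides in replicate 1 and 245 in replicate 2.

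A gene counted as detected at 1 TPM in both libraries. List levels were medians of log2 (TPM + 1), ranked among 10000 random lists of the same size drawn from protein-coding genes, with the central 95% of these as bounds. Each of 11 lists of other cell types was compared with the HSC genes in each library, leaving out shared members. A gene pair was called ordered when both libraries gave the same direction and the deposited intervals did not overlap in either. Ratios used a pseudocount of 0.1. Genes were called apart between replicates at a mean of at least 1 TPM, a difference over 2-fold and intervals that did not overlap. List differences between replicates were ranked among random lists matched on mean expression. Dispersion was estimated with edgeR from rounded counts of genes with at least 10 counts in both libraries. With 2 libraries in 1 group there was no differential test, and the smallest p that an exact sign-flip permutation over the replicates can give is 0.5.

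The gene lists were HSC genes, sorting antigens, stem cell transcription factors, multipotent and lymphoid-primed progenitor genes, erythroid, megakaryocyte and platelet, neutrophil and granulocyte, monocyte and macrophage, dendritic cell, mast cell with basophil and eosinophil, B cell, T cell, natural killer and innate lymphoid, stromal and osteolineage, endothelial, Hox cluster, proliferation, cyclin-dependent kinase inhibitors and quiescence, glycolysis, oxidative phosphorylation, mitochondrially encoded, epigenetic regulators, cytokine and niche receptors, self-renewal and signalling, immediate early and heat shock, interferon response, MHC class I and antigen presentation, Y-linked and Xist, apoptosis regulators, imprinted genes, and small and structural noncoding RNA. These lists, the 40 gene pairs, the 28 isoform genes, the measures named above and most alternatives were chosen before the data were examined. Named genes were the 20 of highest mean TPM, the 4 highest and 2 lowest members of each list, all sorting antigens, the first 15 stem cell transcription factors, the pairs, the isoform genes, the Y-linked genes with Xist, and the 10 genes furthest apart in each direction with a mean of at least 5 TPM, as far as length allowed. A few genes that this rule takes are not named in the text, and a few list members are not drawn in the plot of list members, but all count in the list results. Prtn3, Ctsg, Ermap, Nr4a1 and Eef1a1 lie outside this rule and were chosen after their values were seen.

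Alternatives were other thresholds, pseudocounts, backgrounds, posterior means, FPKM, CPM without division by length, DESeq2 size factors, and each library alone. Rescaling of TPM over protein-coding genes, a length minimum of 300 nucleotides, removal of length and GC trends, centred ratios, TMM-scaled counts and lists without shared members were chosen after seeing the data. The steps were tested on simulated data. A coefficient of variation of 0.2 was recovered as 0.198 where no gene was changed. With 200 genes changed 4-fold, 0.2 was recovered as 0.228 and 0.1 as 0.152, so the estimate also holds the spread of changed genes. Lists of 20 genes shifted by 1 on the log2 scale were found in 100% of draws against 5.5% of unshifted lists. These were random genes with simulated ratios that were independent between genes. Markers of a cell type can move together, so the 5.5% is not an error rate for the real lists. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.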

Results

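Total RNA was sequenced from mouse hematopoietic stem cells (HSC), the bone marrow cells that give rise to every blood lineage. The cells came from male C57BL/6J mice aged 5 to 6 weeks. There was 1 group of 2 biological replicates. The comparisons are between genes and gene groups within the libraries and between the replicates. Replicate 1 held 27901074 counts and replicate 2 held 48490188. A gene with 0 counts could lie at up to 3 counts, a floor of 0.108 CPM (counts scaled to the library total) in replicate 1 and 0.0619 in replicate 2. Such floors, and the intervals used below, cover counting error only. Values are in TPM, which divides counts by effective transcript length and then scales them to a constant sum over all features. They are given as mean ± SD over the replicates (n = 2) unless a library is named. The surface gate used to sort the cells is not given in the sources used here. Positions are on GRCm38.

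In these cells 10230 genes had at least 1 TPM in both libraries, of which 9443 were protein-coding. The remainder included 242 processed pseudogenes, 88 small nucleolar RNA genes, 86 long intergenic noncoding RNA genes and 31 small nuclear RNA genes. In replicate 1 alone 10905 genes reached this level, and in replicate 2 alone 10922. The cut of 1 TPM was strict for protein-coding genes, since small noncoding RNA held most of the TPM, as given next. With TPM rescaled over protein-coding genes 12811 genes reached 1 TPM in both libraries, and 13913 had at least 10 expected counts in both. A gene below 1 TPM is thus not necessarily absent.

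Small and structural noncoding RNA took 78.9% ± 3.40 of all TPM (SD, n = 2), and protein-coding genes took 18.3% ± 2.83. Small nuclear RNA, the RNA component of the spliceosome, held 36.7% ± 6.15 of TPM. The class of 7SK and signal recognition particle RNA held 22.5% ± 1.99, and small nucleolar RNA, which guides chemical modification of ribosomal RNA, held 15.6% ± 0.604. Ribosomal protein genes held 3.62% ± 0.419 and mitochondrially encoded genes 0.954% ± 0.209. Histone genes held 0.813% ± 0.0664. Hemoglobin genes held 0.00283% ± 0.000922. As a share of counts the order turned: protein-coding genes held 84.1% ± 3.58 and small and structural noncoding RNA 10.2% ± 3.67.

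**Figure D1:**
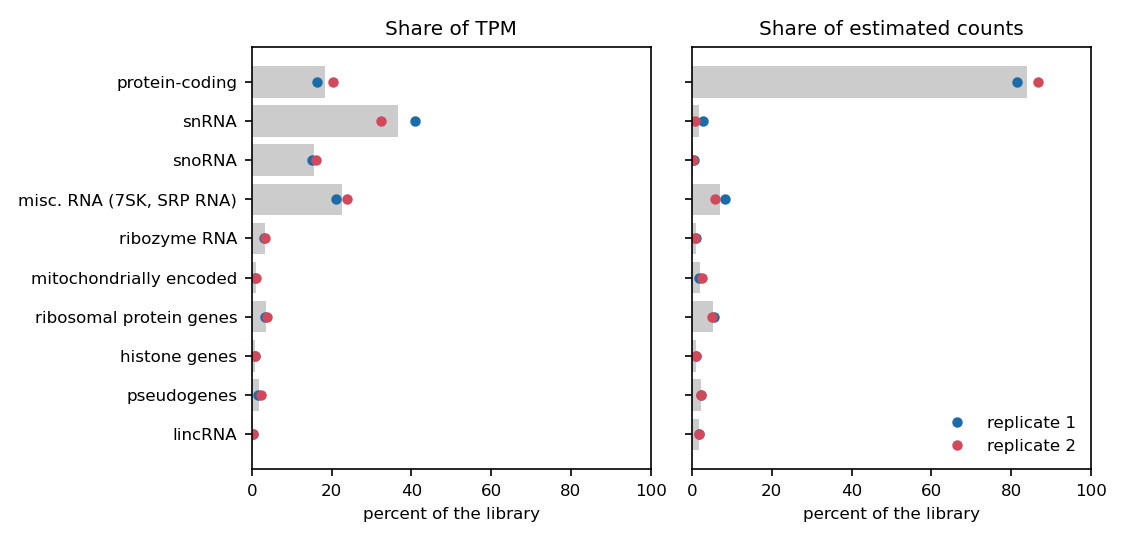
Share of TPM (left) and of estimated counts (right), in percent of the library, for each RNA class. Bars are means and points are the replicates (n = 2), with protein-coding genes at 18.3% of TPM and 84.1% of counts and small nuclear RNA (snRNA) at 36.7% of TPM.

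The most abundant transcript was Rn7sk (chromosome 9, 78175303 to 78175633), the 7SK RNA that holds the elongation factor P-TEFb inactive, at 144806 ± 5745 TPM. Next came the small nucleolar RNA Gm22422 at 59264 ± 24156 and the small nuclear RNA Gm22513 at 47149 ± 18256. Rnu2-10, a U2 spliceosomal RNA, stood at 39000.2 ± 1956, and Rpph1, the RNA of ribonuclease P, at 23875 ± 6109. Rmrp, the RNA of ribonuclease MRP, reached 8393 ± 3485. All of the 20 most abundant features were small or structural noncoding RNA, and together they held 64.8% ± 1.12 of TPM. For 13 of these 20, among them the U1 and U2 copies, the count estimate carried a posterior SD above 0.1 of the count in at least 1 library, so values of single copies are loose. Among protein-coding genes, the mitochondrially encoded mt-Atp8 (3143 ± 157) and mt-Co1 (2815 ± 1248) led, followed by the translation elongation factor Eef1a1 (2616 ± 623). By counts Eef1a1 exceeded Gm22422, with 273113 against 25036 in replicate 1 and 527716 against 16386 in replicate 2. The TPM rank of short features such as Gm22422 thus depends on division by a small effective length. Of the 20 highest protein-coding genes, 12 encode ribosomal proteins. The neutrophil calcium-binding protein gene S100a8 (1074 ± 608) and the chaperone gene Hspa8 (815 ± 317) also stood among them.

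Most genes of the HSC list were expressed, at levels that ranged widely. Cd34, a surface sialomucin of progenitors (chromosome 1, 194938819 to 194961279), stood at 156 ± 14.99 TPM, and Angpt1, which encodes the ligand angiopoietin-1, at 100.2 ± 19.4. Txnip, a regulator of redox state and glucose uptake, reached 72.5 ± 7.40 and Ifitm1 54.6 ± 4.86. Of the 28 genes of the HSC list, 25 had at least 1 TPM in both libraries, with a list median of 4.97 ± 0.718. The lowest members were Slamf1, which encodes the SLAM family antigen CD150, at 0.425 ± 0.00707 TPM from 92 and 148 counts, and Hoxb5 at 0.15 ± 0.156 from 6 and 56 counts. Ranked among 10000 random lists of protein-coding genes of the same size, the HSC list lay at percentile 99.9. Against all genes with any TPM the percentile was 97.1 and lay within the central 95% of random lists. Of all 31 gene lists 18 lay above the central 95%.

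Among the antigens used to sort stem and progenitor cells, 14 of 17 were expressed in both libraries, with a list median of 11.3 ± 1.41 TPM and a percentile of 100 among random lists. The leukocyte phosphatase gene Ptprc (CD45) stood at 67.0 ± 0.849. The receptor gene Flt3, a marker of multipotent progenitors, stood at 55.5 ± 3.34, and Kit, the stem cell factor receptor gene (chromosome 5, 75574916 to 75656722), at 40.8 ± 6.14. Cd27 reached 33.9 ± 8.92, Cd48 14.2 ± 2.61, Procr 13.7 ± 1.43, Cd9 13.7 ± 4.74 and Ly6a, the gene of Sca-1, 12.6 ± 0.389. Lower levels were seen for Itga2b (7.75 ± 1.85), Fcgr3 (7.10 ± 1.28), Fcgr2b (4.00 ± 0.297), Esam (2.60 ± 0.8697) and the lymphoid receptor gene Il7r (1.35 ± 0.0212). Itga2 (0.845 ± 0.332), Thy1 (0.515 ± 0.346) and Slamf1 stayed below 1 TPM. Cd48 exceeded Slamf1 27.1-fold, with a log2 ratio of Slamf1 over Cd48 of -4.76 ± 0.28 that was -3.59 without division by length and -3.41 with a pseudocount of 1. Flt3 exceeded Kit 1.37-fold, and without division by length the log2 ratio of Kit over Flt3 was -0.01.

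Transcription factors of the stem cell network were expressed at high levels. Lmo2, a bridging factor of the Tal1 complex, stood at 153 ± 32.3 TPM and Myb at 77.2 ± 23.3. Erg followed at 47.9 ± 11.05 and Meis1, a partner of Hox proteins, at 47.4 ± 6.64. Etv6 stood at 26.9 ± 2.16, Hoxa9 at 25.3 ± 0.297, Hlf at 23.2 ± 3.71, Fli1 at 21.7 ± 5.04 and Mecom, the Evi1 locus (chromosome 3, 29951296 to 30548008), at 16.8 ± 0.0636. Runx1 reached 10.2 ± 0.792, Lyl1 8.71 ± 0.205, Tal1 6.63 ± 1.73, Gata2 4.72 ± 1.05, Gfi1 4.26 ± 0.983 and Gfi1b 3.58 ± 0.318. The B cell factors stood lowest, with Ebf1 at 0.045 ± 0.0636 TPM and no count for Pax5. Of this list 31 of 36 members were expressed in both libraries, with a median of 9.53 ± 1.18 and a percentile of 100.

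**Figure D2:**
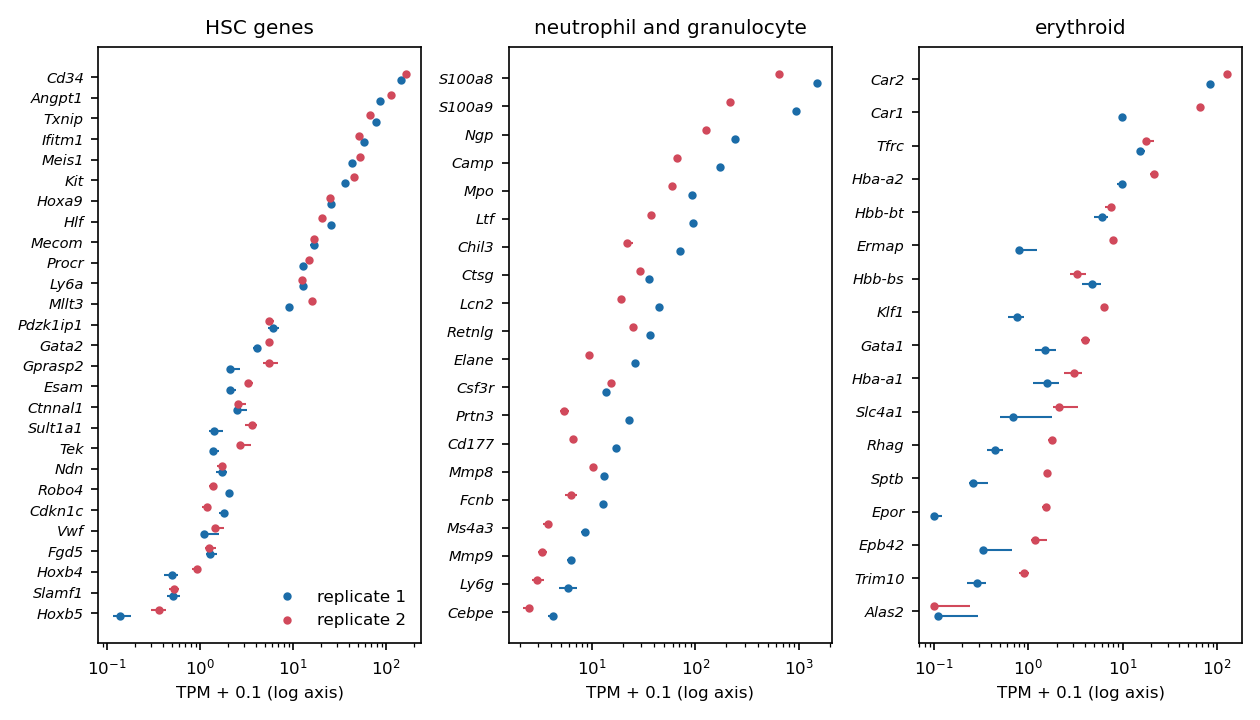
TPM (plus 0.1, log axis) of members of the HSC, neutrophil and granulocyte, and erythroid lists, with points for the replicates (n = 2) and lines for the deposited intervals. S100a8 stands at 1504 TPM in replicate 1 and 645 in replicate 2, and Car1 at 9.74 and 66.9.

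Across pairs of related or contrasting genes, 34 of 40 kept their order in both libraries with intervals that did not overlap. Gata2 exceeded Gata1, the erythroid and megakaryocyte factor, 1.95-fold and the T cell factor Gata3 5.48-fold. The log2 ratio of Gata2 over Gata1, 0.96 ± 0.68, was 2.24 without division by length, and that of Gata2 over Gata3, 2.45 ± 0.41, was 1.66 with a pseudocount of 1 and 1.85 on posterior mean TPM. Spi1, the gene of PU.1, exceeded Gata1 4.56-fold, with a log2 ratio of 2.79 in replicate 1 and 1.59 in replicate 2. Runx1 exceeded Runx2 1.296-fold and Runx3 2.77-fold, the latter a log2 ratio of 1.47 ± 0.51 that was 2.62 without division by length. Mecom exceeded its paralog Prdm16 5.75-fold, Erg exceeded Fli1 2.20-fold and Ikzf1 exceeded Ikzf2 1.73-fold. Erg exceeded Etv6 1.76-fold, a log2 ratio of Etv6 over Erg of -0.81 ± 0.22 that turned to 0.16 without division by length. Cebpa and the erythroid factor Klf1 were not ordered, with log2 ratios of 1.10 in replicate 1 and -1.76 in replicate 2, and neither were Gfi1 and Gfi1b. Of the 39 genes of the Hox clusters 22 had no count in either library, and 4 had at least 1 TPM in both. These were Hoxa9, Hoxa7 (3.53 ± 0.0707), Hoxa10 (2.65 ± 0.205) and Hoxa5 (1.85 ± 0.453). Hoxa9 exceeded Hoxb4 37.3-fold, a log2 ratio of 5.22 ± 0.65 that was 4.04 with a pseudocount of 1. The Hox list had a median of 0 TPM, which was also the lower bound of the central 95% of random lists, so its percentile of 1.69 (3.03 in replicate 1 and 5.04 in replicate 2) rests on ties at 0.

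Markers of 10 of the 11 other cell types lay below the HSC genes in both libraries, and the neutrophil and granulocyte genes lay above them. The calcium-binding protein genes S100a8 and S100a9, abundant in neutrophils, stood at 1074 ± 608 and 585 ± 519 TPM, and the granule genes Ngp and Camp at 184 ± 80.3 and 119 ± 74.5. The lowest members of this list, Ly6g and Cebpe, stood at 4.29 ± 2.06 and 3.23 ± 1.26. All 20 members were expressed, with a median of 23.8 ± 9.75, and the median of the HSC genes lay below theirs by a log2 difference of -1.99 ± 0.75. Monocyte and macrophage genes had a median of 1.29 ± 0.817 with 8 of 18 expressed, led by the lysozyme gene Lyz2 at 244 ± 127 and by Ly6c2 at 18.2 ± 9.49. Mast cell, basophil and eosinophil genes had a median of 1.75 ± 0.191 with 8 of 14 expressed, led by Prg2 (28.2 ± 14.8). Dendritic cell genes had a median of 1.39 ± 0.212 with 6 of 13 expressed, and Siglech had no count. The HSC genes exceeded the monocyte list by 1.43 ± 0.70 on the log2 scale (0.93 in replicate 1 and 1.92 in replicate 2), the mast cell list by 1.11 ± 0.28 and the dendritic cell list by 1.32 ± 0.31. Without division by length the mast cell difference was 1.78.

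Erythroid genes had a median of 2.14 ± 2.02 TPM (0.71 in replicate 1 and 3.56 in replicate 2) with 8 of 18 expressed in both libraries, and the HSC genes exceeded them by 1.09 ± 0.82 on the log2 scale. This difference was 1.67 in replicate 1 and 0.51 in replicate 2, and 1.73 without division by length. The carbonic anhydrase genes Car2 (106 ± 31.8) and Car1 (38.3 ± 40.4) led, followed by the transferrin receptor gene Tfrc (16.5 ± 1.93). Megakaryocyte and platelet genes had a median of 0.935 ± 0.375 with 8 of 18 expressed, and the HSC genes exceeded them by 1.70 ± 0.12, which was 2.47 with a pseudocount of 0.1, 2.69 without division by length and 2.38 on TPM over protein-coding genes. The factor gene Nfe2 stood at 40.9 ± 12.6, Rap1b at 28.3 ± 6.15 and the platelet factor gene Pf4 at 5.77 ± 0.141, while Gp6 had no count. Itga2b exceeded Vwf 6.08-fold, a log2 ratio of 2.60 ± 0.08 that was 1.45 without division by length and 1.99 with a pseudocount of 1.

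B cell genes had a median of 0.0975 ± 0.0247 TPM with 3 of 16 expressed. Ighm, the immunoglobulin heavy chain gene that is also transcribed in early progenitors, stood at 53.8 ± 9.67, and Cd22 had no count. T cell genes had a median of 0.205 ± 0.00707 with 4 of 16 expressed, led by the signalling genes Lat (6.70 ± 0.622) and Lck (5.71 ± 0.226), and Trac had no count. Natural killer and innate lymphoid genes had a median of 0.68 ± 0.156 with 2 of 14 expressed, Nkg7 (9.78 ± 0.594) and Id2 (5.08 ± 0.771). Stromal and osteolineage genes had a median of 0.025 ± 0.0354 with 3 of 17 expressed, led by Runx2 (7.83 ± 0.177). Endothelial genes had a median of 1.24 ± 0.120 with 8 of 14 expressed. Egfl7 stood at 29.5 ± 0.467 and Cdh5 had no count. The HSC genes exceeded these lists by log2 differences of 2.44 ± 0.15 (B cell), 2.30 ± 0.17 (T cell), 1.83 ± 0.05 (natural killer), 2.54 ± 0.23 (stromal) and 2.16 ± 0.27 (endothelial). Their size depended on the pseudocount of 1: with 0.1 they were 4.78, 4.05, 2.71, 5.36 and 3.95 in the same order. Without division by length they were 4.21, 3.74, 3.204, 4.53 and 3.36, and on TPM over protein-coding genes 4.24, 3.73, 2.59, 4.62 and 3.605.

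Genes of multipotent and lymphoid-primed progenitors were also expressed, 10 of 15 in both libraries, with a median of 12.5 ± 0.219 and a percentile of 100. The HSC list had a lower median, 4.97 ± 0.718. The 2 lists hold mostly different genes, so their medians cannot tell stem cells from progenitors. Dntt, the gene of the polymerase that adds nucleotides at antigen receptor joints, stood at 92.3 ± 0.742 TPM and the myeloperoxidase gene Mpo at 75.5 ± 23.5. Rag1 (0.37 ± 0.198) and Ccr7 (0.345 ± 0.148) were lowest. Mpo exceeded the elastase gene Elane 4.73-fold, a log2 ratio of 2.24 ± 0.58 that was 3.61 without division by length.

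**Figure D3:**
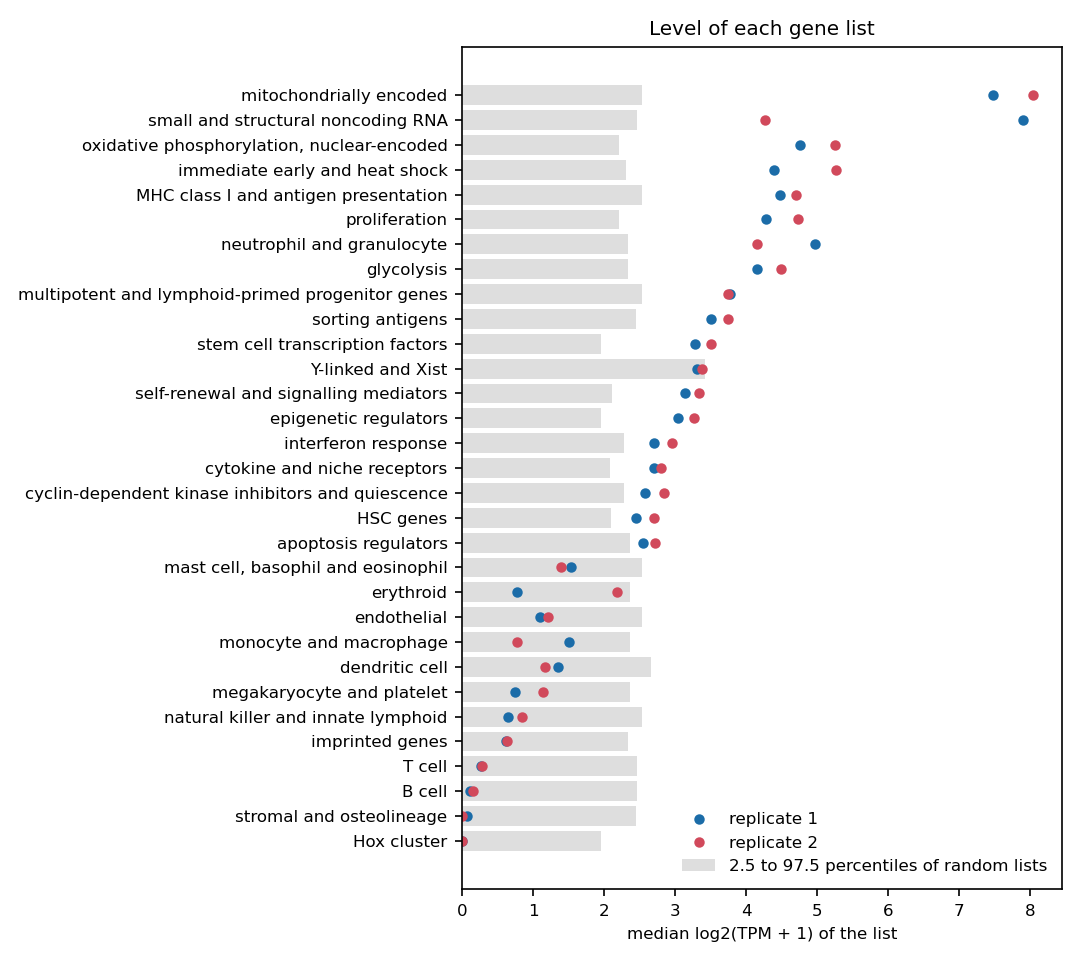
Median log2 (TPM + 1) of each gene list, with points for the replicates (n = 2) and grey bars for the central 95% of 10000 random lists of the same size. Neutrophil genes have a median of 23.8 TPM, HSC genes 4.97 TPM and B cell genes 0.0975 TPM.

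Proliferation genes were expressed throughout, 25 of 25, with a median of 22.0 ± 4.96 TPM and a percentile of 100. The replication clamp gene Pcna stood at 120 ± 21.8, the topoisomerase gene Top2a at 95.1 ± 19.2 and the helicase genes Mcm7 and Mcm6 at 86.7 ± 19.8 and 70.6 ± 16.0. The mitotic genes Plk1 (5.21 ± 3.27) and Foxm1 (2.31 ± 0.622) were lowest. Inhibitors of cyclin-dependent kinases and quiescence genes had a median of 5.95 ± 1.36 with 18 of 22 expressed and a percentile of 99.4, which was 96.4 against all genes with any TPM. Cdkn1b, the gene of p27, stood at 15.8 ± 5.94 and exceeded Cdkn1c 10.4-fold and Cdkn1a 11.1-fold. Cdkn2a and Cdkn2b had no count. The cyclin gene Ccnd2 exceeded Ccnd1 3.05-fold, Myc exceeded Mycn 1.90-fold and Foxo3 exceeded Foxo1 27.95-fold, while Ccnd2 and Ccnd3 were not ordered. The log2 ratio of Cdkn1b over Cdkn1c was 2.67 in replicate 1 and 4.09 in replicate 2. Without division by length the ratio of Cdkn1b over Cdkn1c, 3.38 ± 1.00, was 4.24, that of Cdkn1b over Cdkn1a, 3.48 ± 0.07, was 4.35 and that of Ccnd2 over Ccnd1, 1.61 ± 0.44, was 2.27. With a pseudocount of 1 the ratios over Cdkn1c and Cdkn1a were 2.77 and 2.82, and that of Foxo3 over Foxo1, 4.81 ± 0.22, was 3.35. Cdk4 exceeded Cdk6 3.21-fold, and the log2 ratio of Cdk6 over Cdk4, -1.68 ± 0.15, turned to 0.58 without division by length.

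Glycolysis genes had a median of 19.2 ± 3.33 TPM with 19 of 20 expressed, and nuclear-encoded genes of oxidative phosphorylation 31.6 ± 7.76 with 25 of 25, both at percentile 100. Gapdh (150 ± 44.3), Pkm (104 ± 5.48) and Ldha (54.1 ± 6.51) led the glycolysis list. The ATP synthase gene Atp5b (393 ± 265) and the cytochrome oxidase gene Cox6c (127 ± 55.9) led the other. Mitochondrially encoded genes had a median of 219.8 ± 61.0 with 14 of 15 expressed and a percentile of 100. Ldha exceeded Ldhb 5.00-fold and Hk1 exceeded Hk2 3.61-fold, a log2 ratio of Hk2 over Hk1 of -1.85 ± 0.36 that was -1.15 without division by length. The hypoxia factor gene Hif1a stood at 15.3 ± 4.20, and its paralog Epas1 was listed at 0 in both libraries from 2 and 0 counts.

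Among receptors of cytokines and niche signals 25 of 30 were expressed, with a median of 5.75 ± 0.350 TPM and a percentile of 100. After Flt3 and Kit came the integrin gene Itgb1 (34.8 ± 5.47) and the hyaluronan receptor gene Cd44 (32.1 ± 6.72), with Bmpr1a (0.355 ± 0.120) and Csf2rb2 (0.175 ± 0.0212) lowest. Csf3r, the receptor gene for granulocyte colony-stimulating factor, exceeded Csf1r 13.2-fold. The log2 ratio of Csf1r over Csf3r was -3.03 in replicate 1 and -4.41 in replicate 2, and its mean of -3.72 ± 0.98 was -2.91 with a pseudocount of 1. The erythropoietin receptor gene Epor stood at 0 TPM in replicate 1 and 1.45 in replicate 2. Notch1 and Notch2 were not ordered. Self-renewal and signalling genes had a median of 8.45 ± 0.926 with 27 of 31 expressed and a percentile of 100, led by the beta-catenin gene Ctnnb1 (46.3 ± 6.53). Jak1 exceeded Jak2 1.90-fold and Stat5b exceeded Stat5a 1.20-fold.

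Chromatin and DNA methylation regulators had a median of 7.92 ± 0.930 TPM with 35 of 36 expressed and a percentile of 100. The cohesin gene Stag2 (106 ± 21.1) and the remodeller gene Chd4 (102 ± 29.5) led, and the Polycomb genes Cbx2 (2.12 ± 0.552) and Cbx8 (0.535 ± 0.0778) were lowest. The maintenance methyltransferase gene Dnmt1 exceeded Dnmt3a 7.02-fold, and Dnmt3a and Dnmt3b were not ordered. Tet2 exceeded Tet3 1.54-fold and was not ordered against Tet1. Ezh2 exceeded Ezh1 3.35-fold and Smarca2 exceeded Smarca4 2.36-fold, the latter a log2 ratio of Smarca4 over Smarca2 of -1.24 ± 0.12 that was -0.26 without division by length. Of the Y-linked genes, Eif2s3y stood at 27.6 ± 3.82, Ddx3y at 17.2 ± 0.559, Uty at 9.13 ± 0.389 and Kdm5d at 5.83 ± 1.77, and Xist, the RNA of the inactive X, had no count in either library. This list had a median of 9.13 ± 0.389 with 4 of 5 expressed and a percentile of 96.8.

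Transcript tables showed which isoform carried each gene. Tal1 was carried by Tal1-201 at 97.3% ± 2.96 of its TPM, Flt3 by Flt3-201 at 97.1% ± 0.580, Fli1 by Fli1-201 at 95.5% ± 2.23 and Pkm by Pkm-201 at 88.1% ± 5.76. Kit was split between Kit-201 (53.3% ± 6.21) and Kit-204 (39.7% ± 6.34). Of 28 isoform genes 23 had the same dominant transcript in both libraries. The exceptions were Cd44, Mecom, Etv6, Itga2b and Cdkn1c, of which Etv6 had Etv6-201 at 56.3% in replicate 1 and Etv6-202 at 54.8% in replicate 2. Over 7267 genes with at least 2 annotated transcripts, 74.9% had the same dominant transcript in both libraries. The exact binomial interval of 73.9 to 75.9% treats genes as independent and does not measure spread between libraries or settings.

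The replicates differed in the markers of 4 mature lineages, the neutrophil, monocyte, mast cell and erythroid lists, both as deposited and after TMM rescaling. Across 17917 genes, which are not independent replicates, log2 TPM gave a Pearson r of 0.944 and a Spearman rho of 0.912. Over 13812 protein-coding genes these were 0.972 and 0.963. The spread between the libraries beyond counting noise was a biological coefficient of variation of 0.338 over 13918 genes, which was 0.151 from the DESeq2 median gene-wise dispersion and 0.654 with no count filter. The median log2 ratio of replicate 1 over replicate 2 was -0.29 for protein-coding genes as deposited and -0.08 after TMM rescaling, a shift of 0.22 for each gene. List differences and folds between libraries are given after this rescaling.

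Neutrophil and granulocyte genes were higher in replicate 1 for 20 of 20 members, with a median log2 ratio of 1.33 that lay at percentile 100 of random lists matched on expression. S100a9 (chromosome 3, 90692632 to 90695721) was 5.08-fold higher and S100a8 2.71-fold. The genes of primary granule proteases and peroxidase followed, with Prtn3 at 4.99-fold, Elane at 3.203-fold and Mpo at 1.82-fold. Mast cell, basophil and eosinophil genes had a median of 1.33 and a percentile of 100, with Mcpt8 4.78-fold higher. Monocyte and macrophage genes had a median of 1.02 and a percentile of 100, with Lyz2 2.52-fold higher. Multipotent and lymphoid-primed progenitor genes had a median of 0.52 and a percentile of 100, and the 5 expressed members that no other list held gave 0.23 and 87.7. Without the neutrophil genes alone the other 13 members gave 0.45 and 99.6.

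Erythroid genes were higher in replicate 2, with a median log2 ratio of replicate 1 over replicate 2 of -1.44 and a percentile of 0. Only 2 of the 18 members were higher in replicate 1. Car1 (chromosome 3, 14766216 to 14808368) was 5.86-fold higher in replicate 2, the factor gene Klf1 7.27-fold, Ermap 8.59-fold and Gata1 2.31-fold. Epor had 0 counts in replicate 1 and 299 in replicate 2, at least 57.1-fold higher against a floor of 3 counts per library. Immediate early and heat shock genes were also higher in replicate 2, with a median of -0.37 and a percentile of 1.18. The orphan receptor gene Nr4a1, for example, was 2.12-fold higher. The HSC genes went both ways, with 15 of 28 higher in replicate 1, a median of 0.01 and a percentile of 80.4. In all, 8 of 31 lists lay outside the central 95% as deposited, 9 after TMM rescaling and 10 with a pseudocount of 1.

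**Figure D4:**
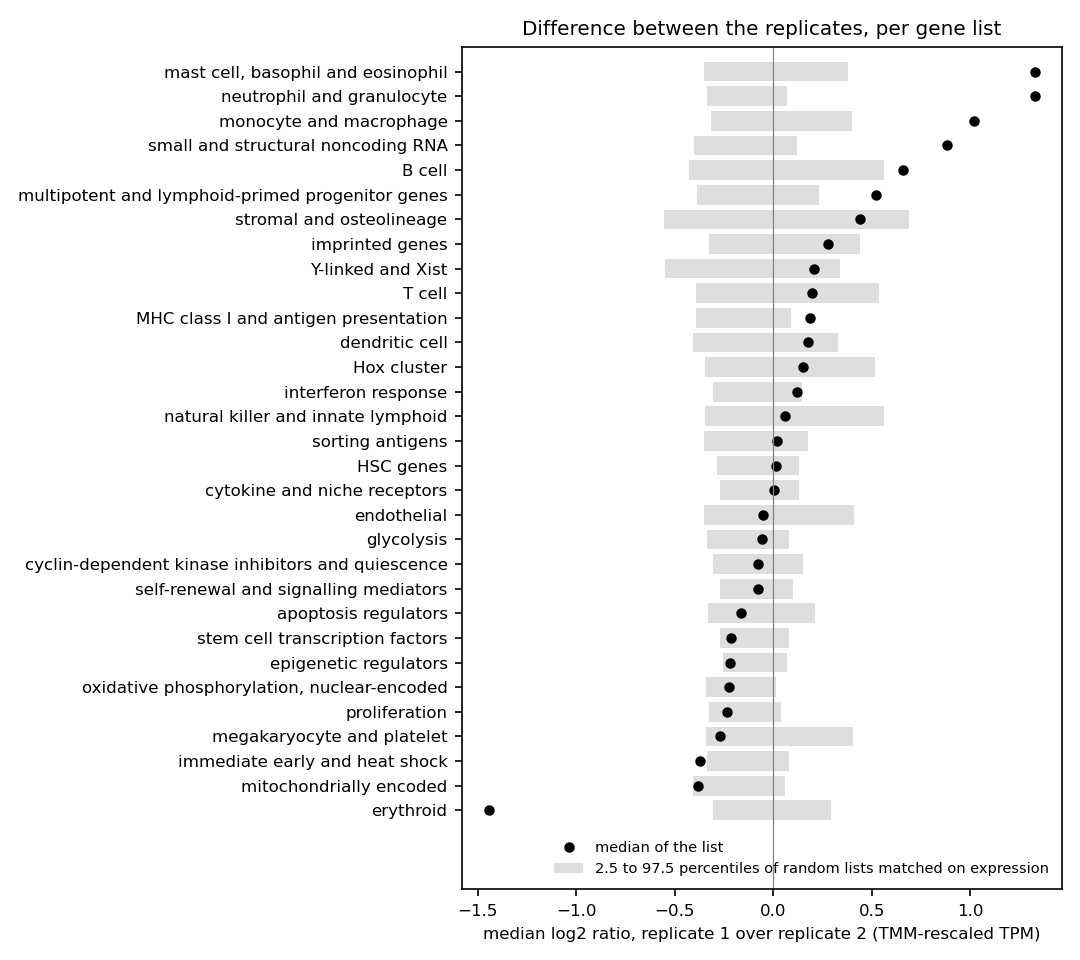
Median log2 ratio of replicate 1 over replicate 2 for each gene list after TMM rescaling (points), with grey bars for the central 95% of random lists matched on expression. Neutrophil genes lie at 1.33, HSC genes at 0.01 and erythroid genes at -1.44.

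Gene by gene, 1281 of 11018 genes differed more than 2-fold between the replicates with intervals that did not overlap, 466 higher in replicate 1 and 815 higher in replicate 2. The balance turned after TMM rescaling, to 662 and 500, and with ratios centred on protein-coding genes, to 780 and 446. By TPM, the genes furthest apart towards replicate 1 were short noncoding RNA listed at 0 in replicate 2, where their effective length was 0. Rny3, a Y RNA, was listed at 9619 TPM in replicate 1 and at 0 in replicate 2, and its TMM-scaled counts differed 19.5-fold, from 967 and 86 counts. The snoRNA gene Gm23734 was listed at 4151 and 0, and its counts differed 5.67-fold. In the other direction stood the noncoding transcript Gm28037, listed at 0 and 121 TPM, and the protein-coding genes Lyrm9 (0.93 and 21.2), Gm2174 (5.43 and 75.5) and Efcab7 (0.75 and 10.2). In TMM-scaled counts Lyrm9 differed 1.38-fold, Gm2174 9.22-fold and Efcab7 2.504-fold. As deposited, small nuclear RNA genes were split 59 to 1 towards replicate 1 and small nucleolar RNA genes 47 to 9. Protein-coding genes were split 205 to 647 as deposited and 349 to 378 after TMM rescaling. Of those apart in TMM-scaled counts as well, 252 were higher in replicate 1 and 186 in replicate 2. With 1 library on each side no p-value can be given.

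**Figure D5:**
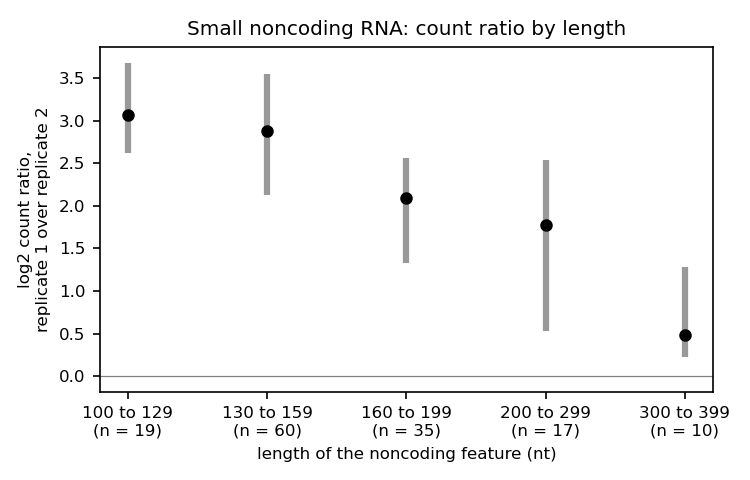
Log2 ratio of TMM-scaled counts, replicate 1 over replicate 2, of small noncoding RNA features by length in nucleotides, with points for medians and bars for quartiles. The median is 3.07 for features of 100 to 130 nucleotides and 0.48 for those of 300 to 400.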

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

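The tests of primary granule genes, erythroid genes, globins, effective length, fragment length and lists without shared members were chosen only after the results were seen, and removal of the length and GC trends was added after the data were examined. The design holds 1 group and gives no biological explanation, so no biological explanation was tested, and other cell types were weighed only as sources of admixed RNA.

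Neutrophil and granulocyte genes were higher in replicate 1, with S100a8 at 1504 against 645 TPM and S100a9 at 952 against 218. The list stayed at percentile 100 after removal of the length and GC trends, which argues against these trends as the whole cause. Bin medians of the trends ranged only from -0.13 to 0.10 on the log2 scale. Genes below the lowest length bin, centred at 630 nucleotides, got no further correction. Mature neutrophils alone would leave the primary granule genes behind. Yet Elane, Mpo, Prtn3 and Ctsg had a median log2 ratio of 1.27 at percentile 100, beside 1.33 for the other 16 members. These 4 genes were uneven, with Prtn3 at 2.32 and Elane at 1.68 above their median and Mpo and Ctsg below it. A lower share of stem cells in replicate 1, with all other cell types raised alike, would raise the erythroid markers too, whereas the erythroid list lay at percentile 0. A lower share with an uneven mix of other cells cannot be judged by that list. The HSC genes had a median log2 ratio of 0.01 at percentile 80.4, and of -0.07 at percentile 35.8 on TMM-scaled counts. A larger share of myeloid cells that include granulocyte progenitors may remain as a hypothesis; 4 of the 20 genes are held by other lists, the list without them gave 1.45 and percentile 100, and the gate that could remove such cells is not given in the sources used here.

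Erythroid genes were higher in replicate 2, with Car1 at 66.9 against 9.74 TPM and Car2 at 128 against 83.5. The list stayed at percentile 0 after removal of the length and GC trends, which argues against these as the whole cause. The same limit for short genes holds here. Red blood cells or reticulocytes would bring globin transcripts first, but summed globin was 21.8 TPM in replicate 1 and 34.9 in replicate 2, a log2 ratio of -0.46 (-0.87 to -0.08 from the interval bounds) beside -1.44 for the list. A larger share of early erythroid progenitors may remain as a hypothesis, and 3 of the 18 genes are held by other lists, without which the median was -1.42 at percentile 0.

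Short noncoding RNA held 78.9% of TPM, and its share of counts was 12.8% in replicate 1 and 7.64% in replicate 2. These features held 10.2% of all counts on average, which is consistent with small effective lengths raising their TPM. Shorter library fragments in replicate 1 may account for the difference between the libraries. The mean fragment length implied by the effective lengths was 193 nucleotides in replicate 1 and 245 in replicate 2. The labels give library size ranges, without a unit, of 172 to 1452 for replicate 1 and 232 to 1000 for replicate 2. Their lower end was thus smaller in replicate 1, but their upper end was larger. The median log2 count ratio of features of 130 to 160 nucleotides exceeded that of features of 300 to 400 by 2.41, and the latter bin held 10 features.

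Outside the main measurement, 15 features in replicate 1 and 24 in replicate 2 had more than 3 counts yet were listed at TPM 0, because their effective length was 0, and they held 715 and 915 counts. Features with numeric identifiers held 8 counts in replicate 1, above the 3 that a count of 0 allows.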

How the results depend on the processing

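Tests on TPM over protein-coding genes, features of at least 300 nucleotides, trend removal, centring, TMM-scaled counts and lists without shared members were chosen only after the results were seen. Detection fell to 5470 genes at 5 TPM, by construction, and was 12811 at 1 TPM over protein-coding genes and 13913 at 10 expected counts. The correlation between replicates, for which a change over 0.02 counted as a move, was 0.917 with a pseudocount of 0.1, 0.848 with 0.01, 0.972 over protein-coding genes and 0.964 on their rescaled TPM. The coefficient of variation between replicates was 0.151 as the square root of the DESeq2 median gene-wise dispersion and 0.654 with no count filter, which adds low-count genes. Genes apart numbered 3484 at 1.5-fold, 315 at 4-fold, 369 at a mean of 10 TPM, 852 among protein-coding genes and 720 when counts also had to differ 2-fold, all by construction. The protein-coding share was 84.1% of counts, 87.0% of TPM without mitochondrially encoded and small noncoding RNA, and 39.7% over features of at least 300 nucleotides. The 20 features of highest count share held 15.1% of counts, and the 20 highest protein-coding genes 13.7% of coding TPM. The same dominant transcript was found for 82.1% of genes at 10 TPM and for 80.2% where it held at least 50% of the gene in either library. For the correlations, the DESeq2 dispersion and the dominant transcripts the cause was not tested. The log2 ratio of Cdk6 over Cdk4 turned to 0.58 and that of Etv6 over Erg to 0.16 without division by length; beyond the effect of length, the cause was not tested.

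With each library alone, detected genes ranged from 10905 to 10922, the protein-coding share from 16.3 to 20.3% and the top 20 share from 64.0 to 65.6%. Alone, each gave 18 lists above the central 95%, 10 cell types below the HSC genes, and 37 to 38 ordered pairs. Log2 ratios of pairs moved in 45 comparisons and not in 157. List levels kept their side of the bounds in 238 comparisons with an alternative, passed a bound in 4 and fell short of it in 7. Differences from the HSC genes moved by more than the spread in 29 of these comparisons and not in 48. List differences between replicates kept their side in 160, passed a bound in 6 and fell short in 1. Depth limited low genes, since 3 counts are 0.108 and 0.0619 CPM.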

Other observations

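The comparison of TPM with TMM-scaled counts and of list members held by other lists was chosen only after the results were seen.

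Genes of antigen presentation were high, with 14 of 15 expressed, a median of 23.1 ± 2.72 TPM (SD, n = 2) and a percentile of 100 among random lists. B2m, the light chain gene of MHC class I, stood at 634 ± 93.8, and the heavy chain genes H2-K1 and H2-D1 at 209.8 ± 0.587 and 128 ± 0.127. This list was slightly higher in replicate 1, with a median log2 ratio of 0.18 and a percentile of 99.6. Interferon response genes had a median of 6.14 ± 0.887 with 19 of 22 expressed and a percentile of 99.7, which was 97.1 without division by length. Ly6e (105 ± 32.0) and Ifitm2 (67.3 ± 3.11) led, and Isg15 (1.03 ± 0.474) was lowest. Immediate early and heat shock genes had a median of 28.6 ± 12.3 with 21 of 21 expressed and a percentile of 100, led by Hspa8, Hsp90aa1 (267 ± 99.0) and Fos (223 ± 15.7).

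Apoptosis regulators had a median of 5.37 ± 0.590 TPM with 15 of 18 expressed and a percentile of 98.8, which was 96.6 without division by length and 93.0 against all genes with any TPM. Mcl1, which encodes a survival factor, stood at 54.7 ± 13.4 and exceeded Bcl2 7.70-fold, and Bcl2 exceeded Bcl2l1 3.22-fold. Without division by length the log2 ratio of Mcl1 over Bcl2, 2.95 ± 0.21, was 1.99 and that of Bcl2 over Bcl2l1, 1.69 ± 0.11, was 3.75. Imprinted genes had a median of 0.555 ± 0.0212 with 8 of 20 expressed and a percentile of 47.2. Gnas, the stimulatory G protein gene, stood at 46.6 ± 9.86 and Grb10 at 4.17 ± 0.750, and Dlk1 had no count. The fixed list of small and structural noncoding RNA had a median of 142.7 ± 169.6 with 11 of 16 expressed and a percentile of 100. It was higher in replicate 1, with a median log2 ratio of 0.88 and a percentile of 100.

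Some protein-coding genes differed in TPM far more than in counts. Of 727 protein-coding genes apart after TMM rescaling, 438 were also more than 2-fold apart in TMM-scaled counts. Tceanc2, chosen after its values were seen, stood at 43.6 and 3.12 TPM from 789 and 1118 counts. Other genes named after their values were seen were apart on both scales. The water channel gene Aqp1 (1.99 and 12.3 TPM) and the metallothionein gene Mt1 (2.96 and 16.9) were higher in replicate 2. The haptoglobin gene Hp (17.8 and 5.51) and Ifitm6 (36.9 and 12.99) were higher in replicate 1. In addition 13 protein-coding genes had 0 counts in replicate 1 and at least 100 in replicate 2, among them Acmsd, also chosen after its values were seen, at least 35.3-fold higher, and 3 had the converse, among them Mrgpra2b, chosen likewise, with 222 and 0 counts and a posterior mean TPM of 2.30 and 0.23. B cell genes had a median log2 ratio of 0.66 at percentile 98.9 after TMM rescaling and 97.3 as deposited, and megakaryocyte genes -0.27 at percentile 5.58, which was 0.76 without members held by other lists.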
